A study of Bos taurus with 27 samples.

How the data were processed

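RNA was measured in biopsies of the superficial cervical lymph node, the node that drains the skin of the neck and shoulder, from cattle of 3 breeds. Per the labels, the 27 arrays fall into 9 groups of 3: Bonsmara, Brahman and Holstein-Friesian animals before tick attachment (baseline), with feeding larvae (larva) and with feeding adult ticks (adult) of Rhipicephalus microplus, the cattle tick. Brahman is a zebu breed, Holstein-Friesian a taurine dairy breed, and Bonsmara a composite breed developed in South Africa. Per the labels' protocols, biopsies went into an RNA stabilising solution, and total RNA was purified, treated with DNase and reverse-transcribed with an aminoallyl nucleotide. The cDNA of each sample was coupled to the red dye Cy5, and a common reference pool of cattle superficial cervical lymph nodes to the green dye Cy3, so each array compares 1 sample with the same pool. The labels call the replicates biological, and do not say whether the 3 stages of a breed were sampled from the same animals.

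The deposited table holds log2 ratios of sample and reference, already normalized by the authors, for 45220 probes on 27 arrays, with 0 missing values. Per the submitters' processing notes, limma was used, and its version, the background correction and the normalization are not given in the sources used here. The base of the logarithm and the direction of the ratio are not written in the file. Base 2 and the direction sample over reference were taken as likely, from the dyes in the labels and from limma's convention of a log2 ratio of red over green. As a check of direction made after the values were seen, 39 of the 50 most variable genes had their longer tail towards higher values and 11 towards lower ones. If the direction were the opposite, every rise and fall in the text would change places. Array medians lay between -0.0095 and 0.0059, and standard deviations between 0.22 and 0.55, so the arrays were centred and not scaled to one spread. Correlations of 2 arrays over all features ran from -0.14 to 0.46, with a median of 0.13. Scanner intensities were not used here, so signal over background is unknown.

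Probes were named through the platform's probe table, with symbols brought up to date through the accessions and synonyms of the RefSeq gene table of the ARS-UCD2.0 assembly, which was used for names only. Of the 45220 probes, 30788 had 1 gene symbol, 0 had several and 14432 had none. Accessions named 20526 probes, an unchanged symbol 9844 and a synonym 369, and 2393 symbols were updated. No genome build is stated for the array, so no positions are given. Probes of 1 gene were averaged, which gave 14495 genes, and each unnamed probe was kept as a feature of its own, which made 28927 features.

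Linear models were fitted with limma 3.58.1 in R 4.3.3 to the deposited log2 ratios, with 1 mean per group and all 27 arrays in 1 fit, so that the 9 groups shared 18 residual degrees of freedom (prior degrees of freedom 3.86). Contrasts between group means were tested two-sided with moderated statistics. P-values were adjusted by the Benjamini-Hochberg method over the 28927 features of each contrast, and an adjusted p under 0.05 was the threshold. The 15 comparisons set larva against baseline, adult against baseline and adult against larva, within each breed and as the mean over breeds, and each pair of breeds at baseline. An F test over 4 differences of responses tested the breed by stage interaction, and the response to larvae or adults was also compared between each pair of breeds. The reference pool cancels in every comparison. Differences are given in log2 units with the standard error (SE) of the fit, whose median for a within-breed difference was 0.16, and group levels as mean ± SD over 3 arrays.

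Gene lists, 37 in number, covered immune cell types, cytokine programmes, stress responses, matrix and stroma, blood vessels, neighbouring tissues and basic cell functions. They were written before the data were examined, as were the design, the alternatives and the rule for named genes. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 37 lists of a comparison. Camera with a correlation estimated from the data, which is far stricter for co-regulated genes, and fry were alternatives. Of the 210 list calls over the 15 comparisons, 7 held with an estimated correlation, and each is named where it is reported. Named genes were the 8 largest rises and the 8 largest falls past the threshold whose arrays did not overlap between the groups, or that moved the same way in all 3 breeds for the mean over breeds, leaving out provisional symbols. Where 0 passed, the 3 smallest p-values in each direction were taken as values only. For each called list, up to 4 members past the threshold were named, or up to 2 by smallest p as values only, and for the interaction the 6 genes with the smallest adjusted p.

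The same code was tested on simulated data with the spread of the real features and arrays, over 28927 features and 5 repeats. For Bonsmara larva against baseline it recovered 28% of genes changed by 0.5 log2 units, 83.6% of those changed by 1 and 98.4% of those changed by 2, with 3.5% false calls. For the mean over breeds, larva against baseline, it recovered 77.2%, 98% and 100%, with 7.7% false calls. For Bonsmara against Holstein-Friesian at baseline the shares were 30.4%, 82.8% and 100%, with 7.9% false calls, above the nominal rate.

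Alternatives fixed beforehand were median centring, quantile normalization, array weights, 1 entry per probe, a fit of only the groups compared, a variance prior with trend and robust estimation, the replicate number as a block, and leaving out each array in turn. A filter on features with missing values was also listed and removed nothing. After the data were seen, a fit without 3 arrays that stood apart and a scaling of all arrays to one interquartile range were added. The 3 arrays are Brahman baseline replicate 2, which had the largest spread, and the arrays labelled Bonsmara larva replicate 3 and Holstein-Friesian larva replicate 3, which lay nearer another breed than their own over 20, 50 and 100 breed features alike. Bonsmara larva replicate 2 did so over 50 and 100 features, Bonsmara adult replicate 2 over 50 and Holstein-Friesian adult replicate 2 over 20, and these were not set apart. All arrays were kept in the reported values. Figures were drawn with matplotlib 3.10.9.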

Results

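The lymph nodes of 3 cattle breeds were profiled before tick attachment, while larvae fed and while adult ticks fed, with 3 arrays in each of the 9 groups. The design asks how the draining node differs between the uninfested and the infested stages, and whether breeds respond alike. With 0 arrays from uninfested animals at the later times, time or age cannot be told apart from tick feeding in any stage comparison. Every value is a log2 ratio of 1 sample to a common pool of lymph node RNA, likely sample over pool, so a group difference of 1 is a doubling if that direction and base hold. The number of arrays limits the precision. P-values rest on the spread between arrays within groups, shared over all 9 groups and moderated across features, not on the groups compared alone. The array labelled Holstein-Friesian larva replicate 3 had a mean correlation of -0.085 with the other arrays of its group, and it lay nearer Brahman than Holstein-Friesian over breed-specific features. It enters every Holstein-Friesian larva value and every mean over breeds given for larvae. The array labelled Bonsmara larva replicate 3 lay nearer Holstein-Friesian (0.60, root mean square log2 distance over 50 breed features) than its own breed (0.95), and it enters every Bonsmara larva value and the same means. In BOLA-DQA2, picked after its values were seen, this array stood at -3.04 and Bonsmara baseline replicate 3 at -3.38. The Holstein-Friesian baseline arrays stood at 0.56, 0.46 and 1.21, so this 1 gene went with the Bonsmara label.

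The first question is what feeding larvae change in the node whatever the breed, as the mean of the 3 breeds' differences. While larvae fed, the extracellular matrix and lymph node stroma lists were higher than at baseline and the cytotoxic and NK cell list was lower, and these calls held with an estimated correlation (adjusted p = 0.0440, 0.0440 and 0.0212). The collagen genes COL1A1, COL3A1 and COL1A2 rose by 1.99 (SE 0.27, adjusted p = 6.19e-04), 1.61 (SE 0.26) and 1.5 (SE 0.25) log2 units. IgCgamma, the constant region of the immunoglobulin G heavy chain, rose by 1.88 (SE 0.40, adjusted p = 0.0197). JCHAIN, which joins secreted immunoglobulin polymers, rose by 1.56 (SE 0.38, adjusted p = 0.0433), a call lost without any 1 of 13 arrays (1.32 to 1.65 in those fits). CXCL9 and CXCL10, chemokines that attract activated T and NK cells, fell by 1.75 (SE 0.27, adjusted p = 0.00182) and 1.31 (SE 0.25). KLRK1, the activating receptor NKG2D, fell by 1.15 (SE 0.13, adjusted p = 1.12e-04).

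In this comparison limma called 351 features, 198 higher and 153 lower, of which 204 were genes, 121 higher and 83 lower. Of the 204 genes, 193 had the same direction in all 3 breeds. They were picked by the mean of the same 3 differences, which by itself favours a shared direction. The list of cytotoxic and NK cell genes was lower, with a median of -0.662 over 25 measured members (camera adjusted p = 9.71e-28), a call that held with an estimated correlation (adjusted p = 0.0212). Of its members 12 fell and 0 rose, and 24 fell when adjusted over the list alone. They included the transcription factor EOMES (-1.05, SE 0.13), the chemokine CCL5 (-1.34, SE 0.30) and the granzyme GZMA (-1.01, SE 0.20). The T cell list was also lower, with a median of -0.265 and 5 of 23 members that fell, 10 when adjusted over the list alone, among them CD7 (-0.79), SH2D1A (-0.69), ZAP70 (-0.61) and CD3G (-0.48). That call was lost with an estimated correlation (adjusted p = 0.132 with an estimated correlation). Of the 20 genes of the type 1 T helper list 5 fell, including CXCL11 (-0.94) and the transcription factor TBX21 (-0.59), and the list had an adjusted p = 0.151 with an estimated correlation. The CXCL11 response differed between breeds, with Bonsmara minus Holstein-Friesian at -3.32 (SE 0.51). That difference exceeded the fall within Bonsmara, so the CXCL11 mean is not a fall shared by all 3 breeds. IDO1, an interferon-induced enzyme that degrades tryptophan, fell by 1.43 (SE 0.22), and the receptor KIR2DS1 of NK cells fell by 1.05 (SE 0.24).

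The extracellular matrix list was higher, with a median of 0.405 over 38 members (camera adjusted p = 7.19e-25), and 16 members rose, 26 when adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.0440). The basement membrane collagen COL4A1 rose by 1.38 (SE 0.20) and SPARC, a collagen-binding matrix protein, by 1.37 (SE 0.24). The lymph node stroma list was higher with a median of 0.201, and 5 of 22 members rose, 9 when adjusted over the list alone, including GREM1 (0.68), desmin DES (0.63), the homeostatic chemokine CCL19 (0.61) and vimentin VIM (0.53). It also held with an estimated correlation (adjusted p = 0.0440). Of 30 genes of blood and lymphatic endothelium 3 rose, von Willebrand factor VWF by 1.00, ACKR1 by 0.65 and ROBO4 by 0.33, and the list had an adjusted p = 0.272 with an estimated correlation.

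Of 26 plasma cell genes 8 rose, 19 when adjusted over the list alone, among them MZB1 (1.48, SE 0.36), TXNDC5 (1.31, SE 0.28) and IRF4 (1.05, SE 0.18), and the median was 0.545. The unfolded protein response list had a median of 0.454, and 6 of its 29 members rose, 21 when adjusted over the list alone, including PDIA4 (1.06), SDF2L1 (0.80), HYOU1 (0.78) and the sensor ERN1 (0.73). Both calls were lost with an estimated correlation (adjusted p = 0.0760 with an estimated correlation for plasma cells and 0.0563 for the unfolded protein response). The B cell list had a median of 0.168, and 1 of its 23 members rose, TNFRSF13B (0.57), with an adjusted p = 0.469 with an estimated correlation. The type I interferon list was lower with a median of -0.339, and 2 of 34 members fell, CXCL10 and the macrophage receptor SIGLEC1 (-1.18, SE 0.24). Its adjusted p = 0.274 with an estimated correlation. Macrophage genes had a median of -0.191 and 2 of 33 fell, SIGLEC1 and MERTK (-0.29), with an adjusted p = 0.409 with an estimated correlation. TRGC6, a T cell receptor gamma constant gene, fell by 0.92 (SE 0.20) within the gamma delta T cell list (adjusted p = 0.135 with an estimated correlation). The plot of list medians per array shows the 6 lists in every group. The count was 215 without Holstein-Friesian larva replicate 1 and 579 without the array labelled Holstein-Friesian larva replicate 3, and 200 with arrays scaled to one interquartile range. The balance of directions rests on single arrays: 151 were higher and 202 lower without Brahman baseline replicate 3, 148 and 155 without Bonsmara baseline replicate 3, 110 and 111 without Brahman larva replicate 2 and 116 and 120 without Brahman larva replicate 3.

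**Figure D1:**
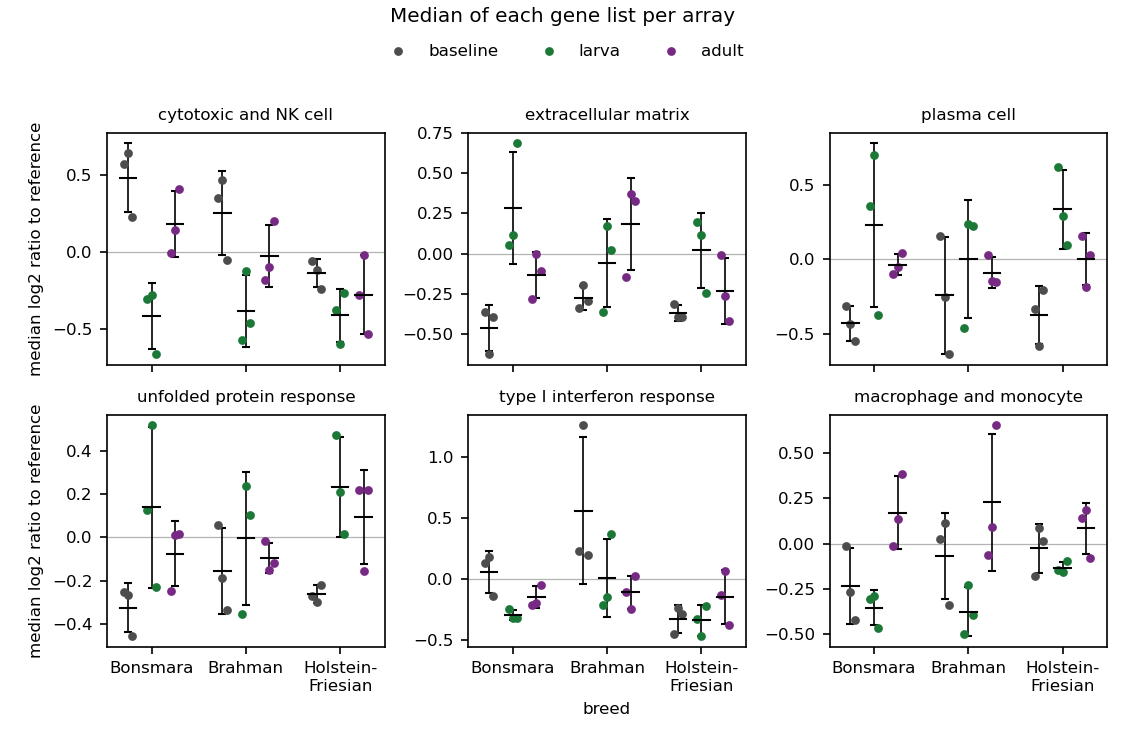
Median log2 ratio to the reference pool (vertical axis) over the members of 6 gene lists on each of the 27 arrays, by breed (horizontal axis) and stage (colour); horizontal lines are means and bars the SD of 3 arrays. The cytotoxic and NK cell list fell from a mean of 0.478 at Bonsmara baseline to -0.416 in Bonsmara larva arrays, and 1 Brahman baseline array stands at 1.262 for the type I interferon list.

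Within Bonsmara, CXCL9, CXCL10, CXCL11 and cytotoxic genes were lower and collagen genes higher in larva than in baseline arrays, and no list call held with an estimated correlation. CXCL9 went from a mean of 2.01 ± 0.74 (SD, n = 3) at baseline to -1.49 ± 1.08 in larva arrays, a fall of 3.50 (SE 0.47, adjusted p = 9.55e-04). CXCL11, IDO1 and CXCL10 fell by 2.83, 2.72 and 2.60 log2 units. Among cytotoxic genes KLRK1 fell by 2.04 (SE 0.23, adjusted p = 2.30e-04), GZMA by 2.11, GZMB by 1.80 and EOMES by 1.68, and TRGC6 and PLAC8A fell by 1.87 and 2.41. IgCgamma rose by 2.89 (SE 0.70, adjusted p = 0.0449), COL1A1 by 2.53 (SE 0.47, adjusted p = 0.00929), COL4A1 by 2.08, COL1A2 by 2.02, COL3A1 by 2.00, SPARC by 1.98, COL4A2 by 1.79 (SE 0.22, adjusted p = 6.07e-04) and elastin ELN by 1.49.

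Limma called 322 features here, 146 higher and 176 lower, of which 186 were genes, 97 higher and 89 lower. Of 25 cytotoxic genes 10 fell, 21 when adjusted over the list alone, with a list median of -1.107 and an adjusted p = 0.0510 with an estimated correlation. Of 38 matrix genes 12 rose, 26 when adjusted over the list alone, with a median of 0.677 (adjusted p = 0.101 with an estimated correlation). Of 22 stroma genes 6 rose, including GREM1 (1.13), THY1 (0.99), CCL19 (0.85) and VIM (0.81), with an adjusted p = 0.101 with an estimated correlation. VWF (1.43) and ACKR1 (0.96) rose among 30 endothelial genes, and that list had an adjusted p = 0.399 with an estimated correlation. In the plasma cell and unfolded protein response lists the members that rose were IRF4 (1.3), CREB3L2 (0.96), ERN1 (1.14) and PDIA3 (0.87), and both lists had an adjusted p = 0.399 with an estimated correlation. CD79A, part of the B cell receptor, rose by 0.97 (B cell list adjusted p = 0.428 with an estimated correlation). Of 20 type 1 T helper genes 5 fell, with TBX21 at -1.21 (adjusted p = 0.306 with an estimated correlation), and SH2D1A was the 1 of 23 T cell genes that fell, by 1.14 (adjusted p = 0.428 with an estimated correlation). With limma fitted to the 6 arrays of this comparison alone, 0 features passed and 5469 had an unadjusted p under 0.05. The count was 134 without Bonsmara larva replicate 2, 168 without larva replicate 1, 174 without baseline replicate 2 and 199 (107 higher and 92 lower) without larva replicate 3, the array that lay nearer Holstein-Friesian, and 1660 with array weights.

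The same comparison was made in the other breeds. In Brahman, limma called 0 features, and 2751 had an unadjusted p under 0.05. The smallest p-values belonged to COL4A2 (1.11, SE 0.22), AMBN (0.55) and GPR173 (0.65) among positive differences and CAMK2A (-0.93, SE 0.15, adjusted p = 0.108), AFAP1L2 (-0.83) and FNTB (-0.52) among negative ones. The cytotoxic list had a median of -0.628, and 9 of 25 members fell when adjusted over the list alone, with an adjusted p = 0.290 with an estimated correlation. KLRK1 differed by -0.89 and EOMES by -0.94, neither past the threshold. The type I interferon list had a median of -0.606, with 19 of 34 members lower when adjusted over the list alone and an adjusted p = 0.573 with an estimated correlation. Without Brahman baseline replicate 2, whose interferon median was 1.262, the median difference was -0.243. The matrix list had a median of 0.243, with COL1A1 at 1.71 (SE 0.47), and the macrophage list one of -0.260, with MERTK at -0.56, each with an adjusted p = 0.573 with an estimated correlation. The count was 120 without Brahman baseline replicate 3, 65 without replicate 1 and 11 without replicate 2.

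In Holstein-Friesian, 1 unnamed feature rose, by 0.88 (SE 0.14, adjusted p = 0.0493), and 1721 had an unadjusted p under 0.05. The plasma cell list had the largest median, 0.725, and 16 of its 26 members rose when adjusted over the list alone, with FNDC3B at 1.06 and PRDM1, the master regulator of plasma cells, at 0.70 (adjusted p = 0.0922 with an estimated correlation). The unfolded protein response list had a median of 0.498 and 17 of 29 such members, with PDIA4 at 1.47 and EIF2AK3 at 0.35 (adjusted p = 0.0922 with an estimated correlation). Matrix genes had a median of 0.395, with COL1A1 at 1.72 and COL4A2 at 0.85 (adjusted p = 0.132 with an estimated correlation). The smallest p-values overall were those of ADAM19 (0.71), DES (0.71), FNDC3B, REG4 (-0.42), ALOX12E (-0.81) and GLYR1 (-0.48), each with an adjusted p = 0.567. The cytotoxic list had a median of -0.337 and the T cell list one of -0.255, with KLRK1 at -0.53 and LCK at -0.47 (adjusted p = 0.567 and 0.441 with an estimated correlation). These values include the array labelled Holstein-Friesian larva replicate 3, and without it 6 features passed. Without all 3 arrays that stood apart, 92 passed in this comparison and 351 in Bonsmara.

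**Figure D2:**
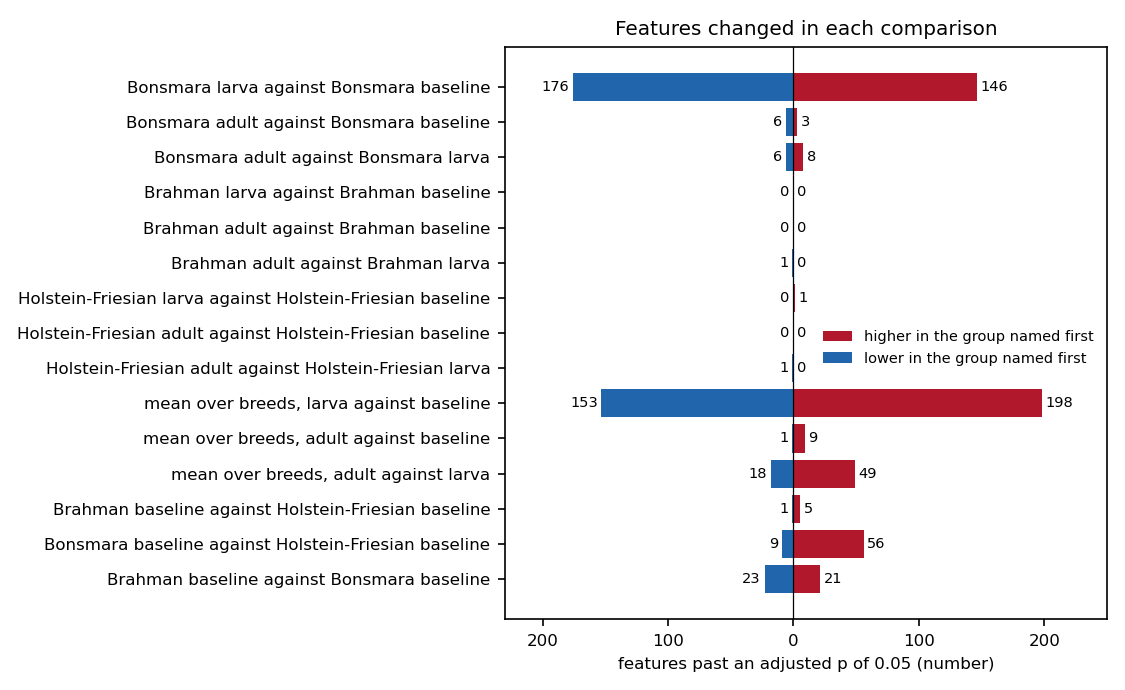
Number of features past an adjusted p of 0.05 (horizontal axis) in each of the 15 comparisons (vertical axis), higher in the group named first to the right and lower to the left. Larva against baseline gave 146 and 176 in Bonsmara and 198 and 153 as the mean over breeds, and the Brahman and Holstein-Friesian stage comparisons gave at most 1.

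Adult arrays were next compared with baseline arrays, to ask how the node differs while adult ticks feed. As the mean over breeds, 10 features passed, 9 higher and 1 lower, and 3313 had an unadjusted p under 0.05. The 7 genes among them included the type VI collagen chains COL6A1 (0.57, SE 0.10, adjusted p = 0.0326) and COL6A2 (0.44, SE 0.08), the neutrophil chemokine CXCL2 (0.40, SE 0.07), the interferon receptor chain IFNAR1 (0.48), the semaphorin co-receptor PLXNA4 (0.52, SE 0.07, adjusted p = 0.00230) and TSR2 (0.77), all of which rose. The matrix list had a median of 0.370, and 20 of 38 members rose when adjusted over the list alone (adjusted p = 0.200 with an estimated correlation). The cell cycle list had a median of -0.381, with 11 of 33 members lower when adjusted over the list alone and the replication licensing factor MCM5 at -0.39 (adjusted p = 0.232 with an estimated correlation). Macrophage genes had a median of 0.233, with the endotoxin co-receptor CD14 at 0.72 and LGMN at 0.70 (adjusted p = 0.200 with an estimated correlation). The count was 91 without Brahman adult replicate 1, 66 without Holstein-Friesian adult replicate 2, 55 without Brahman baseline replicate 3 (15 higher and 40 lower), 23 without Brahman baseline replicate 1 (11 and 12) and 2 without Holstein-Friesian adult replicate 3, so the balance of directions rests on single arrays. With the arrays scaled to one interquartile range it was 1.

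In Bonsmara, 9 features passed, 3 higher and 6 lower. MDGA1 rose by 0.85 (SE 0.15, adjusted p = 0.0419) and PLXNA4 by 0.76, and CXCL11 fell by 2.19 (SE 0.36, adjusted p = 0.0281) and the adenylate kinase AK5 by 0.75. Cytotoxic genes had a median of -0.268, with GNLY at -1.47 and CD8A at -1.03 (adjusted p = 0.423 with an estimated correlation), and matrix genes one of 0.356 (adjusted p = 0.423 with an estimated correlation). With 1 array left out the count ran from 1, without adult replicate 1 or 2, to 60 without baseline replicate 1.

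In Brahman limma called 0 features, with 3360 at an unadjusted p under 0.05. The smallest p-values were those of PLXNA4 (0.66), VWF (1.13), COL4A2 (1.1), CAMK2A (-0.96, adjusted p = 0.0734), FNTB (-0.56) and GDPD4 (-2.30). The type I interferon list had a median of -0.707, with 23 of 34 members lower when adjusted over the list alone, ISG15 at -2.25 and MX2 at -1.81 (adjusted p = 0.330 with an estimated correlation). Without Brahman baseline replicate 2 the median was -0.381. Matrix genes had a median of 0.540, with 13 of 38 members higher when adjusted over the list alone and BGN at 0.50 (adjusted p = 0.330 with an estimated correlation). Endothelial genes had a median of 0.296, with PECAM1 at 0.94 (adjusted p = 0.330 with an estimated correlation). The count was 128 without Brahman baseline replicate 3, 98 without replicate 1 and 13 without replicate 2.

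In Holstein-Friesian limma called 0 features, with 1413 at an unadjusted p under 0.05. The list of inflammatory cytokines and NF-kB genes was higher, with a median of 0.267 over 37 members, and 15 members rose when adjusted over the list alone (camera adjusted p = 2.11e-15). This call held with an estimated correlation (adjusted p = 0.0161). CXCL2 stood at 0.70 (SE 0.12, adjusted p = 0.198), the inflammatory cytokine IL1B at 1.1 (SE 0.24, adjusted p = 0.592) and IL6 at 1.17, none past the threshold singly. The anti-inflammatory cytokine IL10, which is not in this list, stood at 1.07, also not past the threshold. PDIA3 (0.94) and FGF23 (1.3) had the other smallest p-values among positive differences, and UNC93B1 (-0.76), TADA2B (-0.53) and CARD14 (-0.44) among negative ones. The immediate early list, genes that also respond to handling and stress, stood higher in the same arrays, with a median difference of 0.251 and 2 of 27 members higher when adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). In adult replicates 1, 2 and 3 its level was 0.233, 0.033 and 0.224 and that of the inflammatory list 0.295, 0.022 and 0.331. Heat shock genes had a median difference of 0.259 (adjusted p = 0.170 with an estimated correlation). The unfolded protein response list had a median of 0.325, with HSPA5 at 0.80 (adjusted p = 0.170 with an estimated correlation). Without Holstein-Friesian adult replicate 2, 56 features passed.

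The comparison of adult with larva arrays asks how the node differs between the feeding stages. Tick stage cannot be told apart from time or age of the animals here. As the mean over breeds, macrophage genes and the epsilon heavy chain of immunoglobulin E were higher while adult ticks fed than while larvae fed. The macrophage list had a median of 0.450 over 33 members (camera adjusted p = 4.38e-21) and held with an estimated correlation (adjusted p = 0.0459). Of its members 6 rose, 21 when adjusted over the list alone, including the mannose receptor MRC1 (1.48, SE 0.22, adjusted p = 0.0118), the haemoglobin scavenger receptor CD163 (1.12, SE 0.21), C1QB (0.85) and C1QA (0.72). IGHE rose by 3.68 (SE 0.72, adjusted p = 0.0450, 1 probe), from group means of -2.86 ± 2.30, -3.60 ± 1.60 and -1.95 ± 3.87 in larva arrays to 0.75 ± 0.79, 1.84 ± 0.43 and 0.04 ± 0.17 in adult arrays of Bonsmara, Brahman and Holstein-Friesian (SD, n = 3). At baseline IGHE ran from -2.95 to -0.91, -1.85 to -1.37 and -3.64 to -2.33 in these breeds. In Brahman every larva array lay below every baseline array, so part of that breed's difference was a lower larva level. IGHE was not called in adult against baseline as the mean over breeds. CCL26, an eosinophil-attracting chemokine, rose by 1.17 (SE 0.25), CD209 by 1.13 and IL10 by 0.82. Without any 1 of 13 arrays IGHE missed the threshold, and over all fits without 1 array it ran from 3.2 to 4.42, the latter without the array labelled Holstein-Friesian larva replicate 3.

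Limma called 67 features in this comparison, 49 higher and 18 lower, of which 42 were genes. Of the 42, 41 had the same direction in all 3 breeds, which picking by the mean of the same 3 differences favours. Cytotoxic genes had a median of 0.359, and 3 rose, 13 when adjusted over the list alone, KLRK1 (0.69), EOMES (0.68) and CCL4 (0.74), with an adjusted p = 0.0924 with an estimated correlation. The inhibitory receptor HAVCR2 rose by 0.43 with IL10 in the regulatory list (adjusted p = 0.298 with an estimated correlation). SH2D1A rose by 0.63 in the T cell list (adjusted p = 0.310 with an estimated correlation) and properdin CFP by 0.65 in the complement list (adjusted p = 0.295 with an estimated correlation), in which factor B, CFB, fell by 0.65. ELN (-0.62) fell in the matrix list (adjusted p = 0.447 with an estimated correlation) and CCL19 (-0.59) in the stroma list (adjusted p = 0.293 with an estimated correlation). HMGA1 (-0.64), PXDN (-0.49), CCNE1, a cyclin of the G1 to S transition (-0.48), and ADAM19 (-0.41) also fell. The cell cycle list had a median of -0.379, with 20 of 33 members lower when adjusted over the list alone (adjusted p = 0.197 with an estimated correlation). The plasma cell list had a median of -0.239 although IGHE, a member of it, rose (adjusted p = 0.310 with an estimated correlation). The count ran from 2 without Bonsmara adult replicate 3 to 208 without Brahman adult replicate 1, with 10 higher and 14 lower without Brahman larva replicate 1 and 4 and 5 without Brahman adult replicate 3, and was 142 without the array labelled Holstein-Friesian larva replicate 3 and 128 without Holstein-Friesian adult replicate 3. It was 337 with array weights, 251 after quantile normalization, 173 with arrays scaled to one interquartile range and 21 with trend and robust estimation. With the replicate number as a block it was 6, though the labels do not say that a number is 1 animal.

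**Figure D3:**
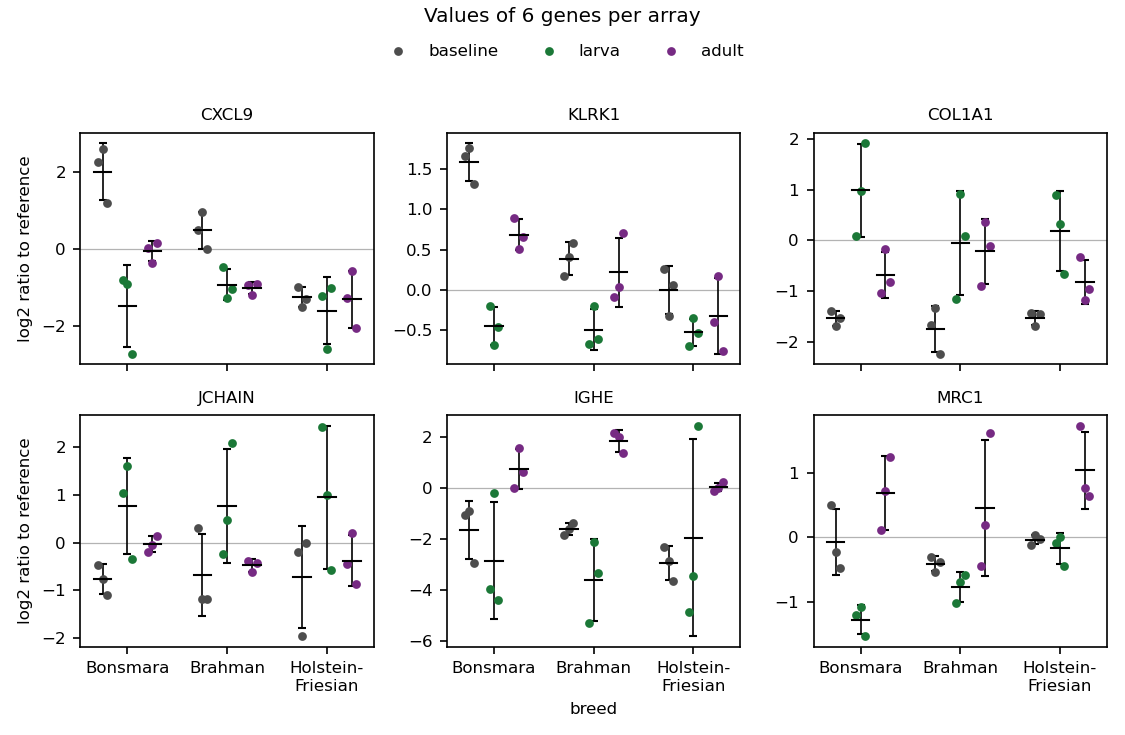
Log2 ratio to the reference pool (vertical axis) of 6 genes on each of the 27 arrays, by breed (horizontal axis) and stage (colour); horizontal lines are means and bars the SD of 3 arrays. IGHE had a mean of 1.84 in Brahman adult arrays and -3.60 in Brahman larva arrays, and 1 Holstein-Friesian larva array stands at 2.44.

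In Bonsmara, 14 features passed between adult and larva arrays, 8 higher and 6 lower. EOMES (1.23, SE 0.23, adjusted p = 0.0490), ARGLU1 (0.93), the DNA polymerase POLI (0.73) and NABP1 (0.66) rose, and COL4A2 (-1.32), CFB (-1.15), PDIA3 (-1.12, SE 0.17, adjusted p = 0.0309) and the laminin chain LAMB2 (-0.59) fell. The macrophage list had a median of 0.483, with MRC1 at 1.98 and SIGLEC1 at 1.93 (adjusted p = 0.238 with an estimated correlation). With 1 array left out, 0 to 3 features passed, and 1291 passed with array weights, 418 after quantile normalization and 117 with arrays scaled to one interquartile range.

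In Brahman 1 unnamed feature fell, by 1.68 (SE 0.24, adjusted p = 0.0154). All 33 cell cycle genes had negative differences, with a list median of -0.697, and 25 fell when adjusted over the list alone, with MCM5 at -0.77 and MCM3 at -0.64 (adjusted p = 0.215 with an estimated correlation). Macrophage genes had a median of 0.582, and 17 of 33 rose when adjusted over the list alone, with the phagocytic receptor MERTK at 0.58 and C1QA at 0.95 (adjusted p = 0.119 with an estimated correlation). SMYD2 (1.06), TMSB4 (0.82), MERTK, HIRIP3 (-0.61), RAN (-0.69) and CHRNB4 (-0.66) had the smallest p-values among genes. In Holstein-Friesian the same unnamed feature that rose in larva arrays was lower in adult arrays, by -1.04 (SE 0.14, adjusted p = 0.00346). There the inflammatory list (median 0.282 over 37 members) and the chemokine list (median 0.142 over 49 members) were higher, and both held with an estimated correlation (adjusted p = 0.0317 for each). Of their members 12 and 8 rose when adjusted over the list alone, with CXCL2 at 0.58, GRO1 at 0.98 and the neutrophil attractant CXCL8 at 1.51. These genes and other chemokines are in both lists, so the 2 calls are not independent. IL10, which is in neither list, stood at 1.33. The immediate early list was higher beside them, with a median of 0.25, a mean level of -0.148 in larva and 0.163 in adult arrays, and an adjusted p = 0.125 with an estimated correlation. SEC23A (0.57), CNDP2 (0.82), the lipid droplet protein PLIN2 (1.35), DENND5B (-0.78), BRMS1L (-0.41) and CD300LG (-0.73) had the smallest p-values among genes, none past the threshold. Without Holstein-Friesian adult replicate 2, 42 features passed, and without the array labelled larva replicate 3 the count was 3.

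The breeds were compared at baseline to ask how their nodes differ without ticks. In each of these comparisons a difference can also come from sequence differences between breeds under the probes. The arrays cannot tell these apart from transcript levels. Before tick attachment, transcripts of CXCL9, CXCL10, CXCL11 and cytotoxic genes were among those higher in Bonsmara than in Holstein-Friesian nodes. CXCL9 was higher by 3.27 (SE 0.47, adjusted p = 0.00241), CXCL11 by 3.26 (SE 0.36, adjusted p = 2.42e-04), IDO1 by 2.49, PLAC8A by 2.39, TRGC6 by 2.34 and CXCL10 by 2.21. GZMB was higher by 2.18 (SE 0.27, adjusted p = 5.92e-04), GZMA by 2.13, GNLY by 1.61, KLRK1 by 1.59 and interferon gamma, IFNG, by 0.93. Of 25 cytotoxic genes 6 were higher, 10 when adjusted over the list alone, and the list median was 0.554 (adjusted p = 0.103 with an estimated correlation). F13A1, a coagulation factor chain made by macrophages, was lower by -1.21 (SE 0.23), and so were UNC93B1 (-0.82), RAB11FIP5 (-0.75), PEG10 (-0.59) and PIP4K2B (-0.48). In total 65 features differed, 56 higher and 9 lower in Bonsmara, of which 33 were genes. The count was 34 to 39 without any 1 Holstein-Friesian array and 19 with arrays scaled to one interquartile range. With only the 6 arrays of the comparison it was 2.

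Brahman and Holstein-Friesian differed at baseline in 6 features, 5 higher in Brahman and 1 lower. The interferon-induced genes UBA7 (1.62, SE 0.28, adjusted p = 0.0369), EIF2AK2 (1.18, SE 0.17, adjusted p = 0.0189) and PARP14 (0.82) and the kinase CAMK2A (1.00) were higher, and F13A1 was lower (-1.37, SE 0.23). The type I interferon list had a median of 0.844, and 28 of 34 members were higher when adjusted over the list alone (adjusted p = 0.160 with an estimated correlation). Without Brahman baseline replicate 2 the median was 0.508. The count was 181 without Brahman baseline replicate 3, 111 without replicate 1, 21 without replicate 2 and 0 without Holstein-Friesian baseline replicate 1, with 2505 at an unadjusted p under 0.05 in that limma fit. It was 4, 1 higher and 3 lower, without Holstein-Friesian baseline replicate 2 and 6, 3 higher and 3 lower, without replicate 3, so the balance of directions rests on single arrays.

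Brahman and Bonsmara differed at baseline in 44 features, 21 higher and 23 lower in Brahman, of which 23 were genes. The peptidase MME (1.15, SE 0.19, adjusted p = 0.0193), CAMK2A (0.87), FCRL4, a receptor of memory B cells (0.85), TMEM218 (0.84), MDGA1 (0.82), ATP6V1D (0.76), CH25H, which makes 25-hydroxycholesterol (0.73), and FNTB (0.60) were higher in Brahman. CXCL11 (-2.01, SE 0.36, adjusted p = 0.0299), GZMB (-1.32), KLRK1 (-1.20), GIMAP8 (-0.88), INTS9 (-0.82), AK5 (-0.79), AP5M1 (-0.78) and PLPBP (-0.76) were lower. The B cell list had a median of 0.431, with CD79A at 0.95 (adjusted p = 0.644 with an estimated correlation). The count was 449 without Brahman baseline replicate 3 (305 higher and 144 lower) and 185 without replicate 1 (130 and 55). Without Bonsmara baseline replicate 1, 2 or 3 it was 75 (16 higher and 59 lower), 54 (16 and 38) and 38 (11 and 27), so the balance of directions rests on single arrays. With arrays scaled to one interquartile range limma called 0 features, with 2653 at an unadjusted p under 0.05.

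Of the 89 genes that fell in Bonsmara between baseline and larva arrays, 25 were also among the 28 genes higher in Bonsmara than in Holstein-Friesian at baseline. Both comparisons use the same Bonsmara baseline arrays, so the lists are not independent. In the opposite direction 1 gene was shared, of 97 that rose and 5 lower at baseline. Independent lists of these sizes would share 0.17 and 0.03 genes, values that ignore the shared arrays, and 100 simulations of unchanged groups with the same shared arrays shared 0, a value that leaves out the effects. Part of the overlap may come from the shared arrays.

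Tests of the responses themselves asked whether breeds differ in them. The breed by stage interaction called 0 features in limma, with 2023 at an unadjusted p under 0.05. CXCL11 and PDIA3 (adjusted p = 0.174 each), LAMB2 (0.227), AK5, CIAO1 and UNC93B1 had the smallest adjusted p-values. The response to larvae differed between Bonsmara and Holstein-Friesian in 2 features, CXCL11 (-3.32, SE 0.51, adjusted p = 0.0236) and 1 unnamed feature (1.51, SE 0.22). Of the 186 genes called in Bonsmara, 159 had the same sign in Brahman and 149 in Holstein-Friesian, where 54.7% and 52.2% of all genes did. Across all 14495 genes, which are not independent replicates, larva responses correlated at 0.25 between Bonsmara and Brahman, 0.23 between Bonsmara and Holstein-Friesian and 0.20 between Brahman and Holstein-Friesian. Adult responses correlated at 0.28, 0.06 and 0.20 for the same pairs, with 50.6% of genes of the same sign between Bonsmara and Holstein-Friesian. Leaving out Brahman baseline replicate 3 gave 36 features for the interaction, and array weights gave 20.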

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

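Tests chosen only after the result was seen were that of a breed-dependent response, the counts without the 3 arrays that stood apart or some of them, the 3 tests of the array labelled Holstein-Friesian larva replicate 3 and the comparison of matrix with macrophage genes.

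Differences between breeds in a response were tested directly. The response to larvae differed between Bonsmara and Holstein-Friesian in 2 features, CXCL11 (-3.32, SE 0.51, adjusted p = 0.0236) and 1 unnamed feature (1.51, SE 0.22), and in 7 gene lists. Among these lists the cytotoxic one had a median difference of -0.74 (adjusted p = 0.764 with an estimated correlation). In the response to adults 12 lists differed between these breeds, with B cell genes at 0.532 (adjusted p = 0.528 with an estimated correlation). Between Brahman and Holstein-Friesian, 5 lists differed in the response to larvae and 13 in that to adults, where type I interferon genes stood at -0.817 (adjusted p = 0.397 with an estimated correlation). Between Brahman and Bonsmara, 8 lists differed in the response to larvae, with matrix genes at -0.524 (adjusted p = 0.903 with an estimated correlation), and 3 in that to adults. None of these list differences passed with an estimated correlation.

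Other splits of the arrays were tested for every count. For the mean over breeds, 1 of 100 splits within breeds, the real one, gave as many features in each comparison. The real counts were 351 for larva against baseline (highest other split 46), 10 for adult against baseline (1) and 67 for adult against larva (49). Chance is an unlikely source of these counts if the arrays of a breed are independent. The splits did not keep replicate numbers together, so they cannot exclude chance if a number is 1 animal. For the interaction, 100 of 100 splits gave at least the 0 features of the real one, and the highest gave 3. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. In Bonsmara the real counts were 322, 9 and 14 and the highest others 1, 1 and 0, for larva against baseline, adult against baseline and adult against larva, with 1 split reaching each. In Brahman they were 0, 0 and 1 and the highest others 2, 4 and 0, with 10, 10 and 1 splits reaching them. In Holstein-Friesian adult against baseline the real count was 0 and the highest other 1 (10 splits), and in adult against larva 1 and 9 (4 splits). At baseline the counts were 6, 65 and 44 for Brahman against Holstein-Friesian, Bonsmara against Holstein-Friesian and Brahman against Bonsmara, and the highest others 5, 1 and 6, with 1 split reaching each. In Holstein-Friesian larva against baseline 4 splits reached the real count of 1, and the split that set baseline replicates 1 and 3 with larva replicate 2 against the rest gave 116 features, which points to a structure of these samples other than the stage.

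More features passed in Bonsmara larva against baseline (322) than in Brahman (0) or Holstein-Friesian (1). The response to larvae differed between Bonsmara and Holstein-Friesian in CXCL11 and 1 unnamed feature, but the interaction, which also covers the adult responses, called 0 features (0 to 36 without 1 array), so a wider difference of the breeds' responses stays open. For a smaller spread between Bonsmara arrays, the residual SD was 1.21 times as large in the nearer breed (1.08 to 1.39 without 1 array). This range spans the bound set beforehand, and the verdict was left open after the range was seen. All breeds shared 1 variance per feature in this fit, with a median SE of 0.162 for larva against baseline in each. This argues against a smaller spread as a source of the higher Bonsmara count in this fit. Bonsmara baseline arrays that stand apart are a candidate explanation. Over the called genes they lay 2.01 times as far from the other baselines as Bonsmara larva arrays from the other larva groups (1.71 to 2.49 without 1 array). These genes were picked by the difference between the same Bonsmara arrays, and the gene set stayed fixed when 1 array was left out. The ratio and its range are therefore no independent support. Arrays that stand apart in the other breeds stay open as part of the cause: Holstein-Friesian gave 6 features without its own such array, 0 without the 2 from other breeds (limma, 1809 unadjusted) and 92 without all 3, which act in part through the shared variance, but Bonsmara still gave 351.

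The array labelled Holstein-Friesian larva replicate 3 lay nearer Brahman (0.49, root mean square log2 distance over 50 breed features) than its own breed (1.27). The tables argue against a noisy array, since the largest own-breed distance of the other larva arrays was 0.95, that of Bonsmara larva replicate 3, which itself lay nearer Holstein-Friesian (0.60), and 0.67 in the rest, and this array was closer than either to Brahman. They also argue against an exchange with a Brahman array, since 0 Brahman arrays lay nearer Holstein-Friesian. A wrong label or an exchange with an array outside these groups may account for it (0.49). Further material from the source of a Brahman array numbered 1 under this label is not excluded, and a crossbred animal was not tested. In genes picked after their values were seen it resembled Brahman replicate 1, with BOLA-DQA2 at -3.83 (-4.23, -4.14 and -3.9 there), LOC618541 at -2.25 and IGHE at 2.44 (-2.18 and 2.17 in Brahman adult replicate 1), and it correlated highest with that adult array (0.43).

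Matrix and stroma genes were higher and cytotoxic genes lower in larva than in baseline arrays, as the mean over breeds, and T cell genes were lower in a call lost with an estimated correlation (adjusted p = 0.132 with an estimated correlation). A lower share of lymphoid cells in the tissue taken would raise matrix and macrophage genes alike only if the other cells kept their proportions. The lists moved apart by 0.63 (SE 0.12), which argues against this even form as the whole cause. A sampling difference in which the other cells do not keep their proportions was not tested and stays open. At the preset correlation, 0 fits without 1 array ended or turned the matrix or the cytotoxic call, so their direction did not rest on 1 array. Both calls were far past the threshold at that setting, so these fits could hardly end them. The calls with an estimated correlation were not refitted without 1 array, and whether 1 array decides them was not tested. Time or age of the animals cannot be told apart from the feeding larvae, since 0 arrays came from uninfested animals at the later times. A change of the node with the feeding larvae is the explanation the design names, and it stays open beside these.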

How the results depend on the processing

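Tests chosen only after the data were seen were the fit without the 3 arrays that stood apart and the scaling to one interquartile range. The filter on missing values removed 0 features, since none was missing, and so tested nothing. The 7 list calls that held with an estimated correlation passed under every alternative run, with the cytotoxic and NK cell list in mean over breeds, larva against baseline, at -0.771 to -0.526, matrix genes at 0.359 to 0.449 and stroma genes at 0.167 to 0.243 in that comparison. Macrophage genes stood at 0.36 to 0.536 for adult against larva as the mean over breeds. In Holstein-Friesian, inflammatory genes stood at 0.267 to 0.335 for adult against baseline and at 0.211 to 0.343 for adult against larva, and chemokine genes at 0.073 to 0.197. Apart from fry and the estimated correlation itself, these alternatives ran camera at the preset correlation. The matrix and cytotoxic calls were far past the threshold at that setting, so the alternatives could hardly end them. Camera with an estimated correlation was not rerun under the other alternatives. Whether the stricter list calls hold there was not tested. COL1A1, KLRK1 and CXCL9 passed under every alternative for larva against baseline as the mean over breeds. Of the 146 gene calls, 93 were lost in at least 1 fit without 1 array, 66 with scaling to one interquartile range, 63 with 1 entry per probe, 31 after quantile normalization, 31 without the 3 arrays, 17 with array weights and 6 after median centring, and 14 of 66 with trend and robust estimation. Of the 80 gene calls within 2 groups, 79 were lost with only the groups compared, a fit with fewer arrays behind its variance. Of the 210 list calls, 203 were lost with an estimated correlation, 182 with fry and 99 in at least 1 fit without 1 array. Where counts changed, the cause was not tested. Signal over background is unknown, so calls at low intensity cannot be set apart.

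In Bonsmara larva against baseline, 1660 features passed with array weights, 511 with 1 entry per probe and 0 with only the groups compared (limma, 5469 at an unadjusted p under 0.05). In Bonsmara adult against baseline the counts were 137 with array weights, 5 after quantile normalization, 18 without the 3 arrays, 0 with scaling (2214 unadjusted) and 0 with only the groups compared (4186 unadjusted). In Bonsmara adult against larva they were 9 after median centring, 418 after quantile normalization, 1291 with array weights, 27 with 1 entry per probe, 4 without the 3 arrays, 117 with scaling and 0 with only the groups compared (4488 unadjusted). In Brahman larva against baseline they were 8 with array weights, 3 with 1 entry per probe and 9 without the 3 arrays, and in adult against baseline 10, 3 and 12. In Brahman adult against larva they were 10 with array weights, 3 without the 3 arrays, 2 with scaling and 0 with only the groups compared (2050 unadjusted).

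In Holstein-Friesian larva against baseline 0 features passed after median centring (1739 unadjusted), after quantile normalization (1695), with 1 entry per probe (2773), with scaling (1526) and with only the groups compared (960), and 92 without the 3 arrays. In adult against baseline 2 passed after quantile normalization, and in adult against larva 6 without the 3 arrays and 0 with only the groups compared (961 unadjusted). As the mean over breeds, larva against baseline gave 587 with 1 entry per probe and 200 with scaling, of which 194 were among the 351. Without the 3 arrays it gave 496, of which 263 were among the 351. Adult against baseline gave 5 after quantile normalization, 21 with array weights, 31 without the 3 arrays and 1 with scaling. Adult against larva gave 251 after quantile normalization, 337 with array weights, 173 with scaling and 21 with trend and robust estimation.

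At baseline, Brahman against Holstein-Friesian gave 2 after quantile normalization, 2 with array weights, 30 without the 3 arrays, 3 with scaling and 0 with only the groups compared (1311 unadjusted). Bonsmara against Holstein-Friesian gave 38 after quantile normalization, 19 with scaling and 2 with only the groups compared. Brahman against Bonsmara gave 1 after quantile normalization, 21 with array weights, 23 with 1 entry per probe, 0 with scaling (2653 unadjusted) and 0 with only the groups compared (2160 unadjusted). The share of features higher in Brahman than in Bonsmara was 47.7% and went to 100% after quantile normalization (1 feature), 71.4% with array weights, and 21.3%, 29.6% and 28.9% without Bonsmara baseline replicate 1, 2 or 3, and 70.3% and 67.9% without Brahman baseline replicate 1 or 3. In Brahman against Holstein-Friesian it went from 83.3% to 100% with quantile normalization and with scaling, and to 25% and 50% without Holstein-Friesian baseline replicate 2 or 3. The interaction gave 3 after quantile normalization, 20 with array weights and 4 without the 3 arrays.

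With the replicate number as a replicate block, Bonsmara adult against baseline gave 5 features and adult against larva 7, and Holstein-Friesian larva against baseline 0 (limma, 1763 unadjusted). As the mean over breeds, adult against baseline gave 5 and adult against larva 6 (4 higher and 2 lower, and 67 without it) with the replicate block, and Brahman against Holstein-Friesian at baseline gave 3. Of the 146 gene calls 47 were lost with this block, and 3 of the 210 list calls. Arrays of the same breed and replicate number correlated at -0.024 to 0.163 in Bonsmara, 0.003 to 0.181 in Brahman and -0.30 to 0.154 in Holstein-Friesian. Between breeds at baseline, arrays of the same number correlated at -0.064 to 0.048. Not every pair of the groups compared was over 0.1, and by this bound the arrays were treated as unpaired in the reported values. Whether a number is 1 animal stays open. Between Bonsmara and Brahman adult arrays, all 3 pairs of the same number were over 0.1 (0.254, 0.11 and 0.234, against -0.225 to 0.022 for other numbers). Of the other 24 pairs of the same number between breeds at one stage, 0 were. These adult arrays enter the means over breeds, the interaction and the comparison of responses to adults, which treat them as independent. The cause of these correlations was not tested, and the block, set within breeds for the stage comparisons, does not hold these pairs. Their bearing on those results was therefore not tested. The splits of arrays did not keep the numbers together. As a hint from the data, not the design, an array correlated best with its own number in another stage in 12, 13 and 6 of 18 cases per breed, where chance gives 6. Single genes picked after their values were seen also followed the number, such as BOLA-DQA2 at -4.23, -4.14 and -3.9 in the 3 stages of Brahman replicate 1 and 0.15 to 0.76 in Brahman replicates 2 and 3. LOC618541 stood at 1.54, 2.44 and 0.77 in Bonsmara replicate 3 and at 1.25, 0.94 and 1.11 in Holstein-Friesian replicate 1. The other arrays of these breeds reached at most 0.3. BOLA-DQA2 did not follow the number in Bonsmara (-1.52, -4.15 and -3.84 in replicate 1). If a number is 1 animal, the reported p-values leave that pairing out.

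Without 1 array, counts ran from 134 to 278 in Bonsmara larva against baseline, 1 to 60 in adult against baseline and 0 to 3 in adult against larva (limma, 2562 unadjusted at 0). In Brahman they ran from 1 to 120 in larva against baseline, 1 to 128 in adult against baseline and 1 to 7 in adult against larva. In Holstein-Friesian they ran from 0 to 6 in larva against baseline, 0 to 56 in adult against baseline and 0 to 42 in adult against larva. As the mean over breeds they ran from 215 to 579 for larva against baseline, 2 to 91 for adult against baseline and 2 to 208 for adult against larva. At baseline they ran from 0 to 181 in Brahman against Holstein-Friesian, 34 to 92 in Bonsmara against Holstein-Friesian and 38 to 449 in Brahman against Bonsmara, and for the interaction from 0 to 36. In each fit the group left with fewer arrays is assumed to vary like the others.

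Directions that reversed were those of lists with small medians and of single genes not past the threshold, and the cause was not tested. In Brahman adult against baseline the ribosomal list (-0.075) turned in camera with array weights, where its median stayed negative (-0.008), and its median went to 0.024 without the 3 arrays and without Brahman baseline replicate 2 (-0.142 to 0.024 without 1 array), and ATP5MF to 0.01 with 1 entry per probe. In Brahman against Bonsmara at baseline the ribosomal list went to -0.028 without the 3 arrays and without Brahman baseline replicate 2 (-0.028 to 0.177 without 1 array). RPL3L went to 0.08 in Bonsmara adult against baseline and -0.06 in Bonsmara against Holstein-Friesian at baseline, and FOXM1 to 0.01 in Holstein-Friesian adult against baseline, with 1 entry per probe. The cell cycle list went to -0.056 in Brahman larva against baseline without Brahman larva replicate 1 (-0.056 to 0.32), and the interferon list to 0.036 in Brahman adult against larva without larva replicate 3 (-0.253 to 0.036). RPL10L went to -0.08 in Holstein-Friesian adult against baseline without baseline replicate 1 (-0.08 to 1.43). In Holstein-Friesian adult against larva the ribosomal list went to -0.004 without larva replicate 1 and -0.007 without larva replicate 3 (-0.007 to 0.133), and the oxidative phosphorylation list to -0.008 without adult replicate 3 (-0.035 to 0.161). Without the array labelled larva replicate 3, and without the 3 arrays, the heat shock list there went to -0.085 (-0.085 to 0.313 without 1 array) and the oxidative phosphorylation list to -0.035.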

Other observations

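The test of a type 2 shift was chosen only after the result was seen. In Holstein-Friesian adult against baseline, 26 of 29 heat shock genes had positive differences, with a list median of 0.259, HSPA5 at 0.80 and the collagen chaperone SERPINH1 at 0.82 (adjusted p = 0.170 with an estimated correlation). The chemokine list had a median of 0.132 there, with 9 of 49 members higher when adjusted over the list alone and CXCL3 at 0.84 (adjusted p = 0.113 with an estimated correlation). In the adult against larva comparison as the mean over breeds, B cell genes had a median of -0.279, with 6 of 23 lower when adjusted over the list alone and CD79A at -0.52 (adjusted p = 0.204 with an estimated correlation). Genes of MHC class I presentation had a median of 0.292 in Bonsmara against Holstein-Friesian at baseline, with ERAP1, which trims peptides for presentation, at 0.46 (adjusted p = 0.103 with an estimated correlation). Lists of neighbouring or other tissues and of apoptosis were not called in any of the 15 comparisons: the smallest adjusted p was 0.0866 for adipocyte, 0.0642 for apoptosis, 0.0632 for epidermis, 0.154 for erythroid and 0.159 for skeletal muscle genes.

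IGHE was not called in adult against baseline as the mean over breeds. A hypothesis is that its higher transcript level in adult than larva arrays may go with a type 2 shift of the node. The type 2 T helper list was higher, with a median of 0.053 over 24 members and 1 that rose, CCL26, 2 when adjusted over the list alone, but its adjusted p was 0.108 with an estimated correlation, and without Brahman larva replicate 1 its median was 0.013 and the call was lost. The test leaves the hypothesis undecided.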
